A study of Mus musculus with 2 samples.

How the data were processed

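Nuclei isolated from snap-frozen mouse SVZ tissue were counted in 2 libraries, 1 of control mice and 1 of MIP mice, with groups taken from the labels. The deposited values are raw UMI counts per gene and barcode for 32285 genes, made by the authors with Cell Ranger 5.0.1 per the file headers and the submitters' processing notes, on the mouse build mm10 per the processing notes. Whether animals were pooled, their sex, the time of day and the filter that called barcodes are not given in the sources used here. Gene positions are 1-based, from GENCODE release M21 of the same build; 37 of 37 genes looked up were matched by identifier.

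Barcodes with fewer than 500 genes (0 control, 204 MIP) or more than 5% mitochondrial UMIs (114 and 48) were left out. The lowest depth in the files was 1027 UMIs in the control and 590 in the MIP library. Doublets were scored per library with Scrublet in Scanpy 1.11.5. Its automatic threshold marked 0 barcodes in both libraries, so the fallback fixed beforehand was used, which removed the top-scoring share of 0.8% per 1000 barcodes: 2302 control and 1221 MIP barcodes. This share is larger in the larger library, and remaining doublets and free RNA both bear on low values in a class. Kept were 14548 control nuclei, or 85.8%, with a median of 5638 UMIs, and 10893 MIP nuclei, or 88.1%, with a median of 6018 UMIs.

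Both libraries were clustered together on counts per 10000 after a log transform, with 3000 variable genes chosen within each library, 40 principal components, exact 20 nearest neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Python 3.11.15). Mitochondrial, ribosomal protein and haemoglobin genes and the sex-linked genes Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y were kept out of the variable genes. The 37 clusters were named from fixed marker genes, so a class name means resemblance only. Clusters with under 3 detected markers stayed unnamed. So did clusters with a median depth below the library's divided by 3 and no marker among the top 10 genes. A further check of the leading genes against the name could not fail, since the name was taken from those same genes. Unnamed clusters held 14.4% of control and 17.1% of MIP nuclei, beside the low-depth clusters. With 1 library per group, a cluster that is mostly from 1 library can be that library and not a type. The 9 classes with at least 100 nuclei in each library whose clusters passed the marker check were compared.

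Shares of nuclei have exact Clopper-Pearson intervals. Raw UMIs were summed over the nuclei of a class in each library, divided by the class total, and compared as a log2 ratio of MIP to control with the exact interval of a ratio of 2 Poisson counts. Where a library had 0 UMIs, a bound was set against 3 UMIs over the class, which leaves out the counting error of the other library; the exact interval, which includes it, is given beside. No test was made, since nuclei are not replicates. Named genes were the 10 highest and 10 lowest in the MIP library in astroglia, cycling progenitors, neuroblasts and the oligodendrocyte lineage, and 5 and 5 elsewhere. They were ranked by the interval bound nearest to a ratio of 1, among genes with at least 60 UMIs in the higher library and, within classes, at least 20% of the level of the class with the highest value in at least 1 library. This last limit was not used over all nuclei. Mitochondrial, ribosomal protein and haemoglobin genes were left out of the ranking, and of sex-linked genes only the set named above. Other X-linked genes, among them Jpx, Nexmif, Mid1 and Tspan7, and the Y-linked Gm29650 were ranked, and Tsc22d3, Dcx and Gpr34 are X-linked too. Genes outside these limits have no rank, however far their interval lies from a ratio of 1. Some genes that the rule names are not reported here. Members of the lists with the largest ratios and a set of 12 genes of interest were added by the same rule. Other members named, such as Nr3c1, Arntl, C1qb, Hmgcs1, Mertk, Dlx1 and those of contrary direction, were picked after their values were seen.

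Of 33 gene lists, each was described where at least 5 members had at least 20 UMIs over both libraries. A member counted as higher or lower at a ratio of 1.5. The median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The groups, filters, markers, lists, naming rule and the alternatives below were fixed before the data were examined, except where said otherwise. Which of the lists are described in which class was chosen after the values were seen. For cell cycle shares each nucleus was thinned to 2000 UMIs and shallower nuclei were left out.

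The scripts were tested on simulated counts drawn from the real depths with 200 genes changed. The interval of unchanged genes covered their true ratio in 96.0% of 13755 genes for oligodendrocyte precursors, 96.3% of 10734 for microglia and 96.0% of 14754 for astroglia. In each class 100% of 2-fold and 100% of 4-fold changes were recovered. The changed genes were drawn only from genes with higher counts, so recovery at few UMIs was not tested. Of 100 lists without a change 4, 7 and 5 lay outside the 95% range. The simulated counts followed the Poisson model that the interval assumes, and these lists were random genes, as were the reference lists. The coverage and the list result therefore check the scripts only. Variation between nuclei or animals and real lists of co-expressed genes were not tested.

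Alternatives tried were a minimum of 1000 genes, no doublet removal, Leiden resolutions of 0.5 and 2, clusters built on either library alone, classes from marker scores of single nuclei, TMM scaling factors of edgeR 4.0.16 in R 4.3.3 (scaling only), a total without mitochondrial, ribosomal protein, haemoglobin genes and Malat1, thinning to 2000 or 1000 UMIs, means over single nuclei, list minimums of 100 and 1 UMIs, and at least 2 cell cycle UMIs. Shares without the low-depth clusters and ratios with the clusters of a class weighted equally were added after seeing the data. Plots were drawn with matplotlib 3.10.9.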

Results

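Nuclei of the mouse subventricular zone (SVZ), a germinal zone beside the lateral ventricle that supplies neurons and oligodendrocytes after birth, were profiled by single-nucleus RNA sequencing. Mice were assigned on postnatal day 5 to a control group or to MIP, a model of intestinal perforation, and tissue was taken 48 h later, on postnatal day 7. Each group was represented by 1 library, and how many animals each library holds is not stated in the sources used here. The comparison asks how the SVZ differs after an intestinal injury early in life. The control library held 16964 barcodes with 146730970 unique molecular identifiers (UMIs), and the MIP library 12366 barcodes with 100823376 UMIs. Median depth was 6154 UMIs and 2898 genes per barcode in the control library and 6351 UMIs and 2834 genes in the MIP library. After filtering, 14548 control and 10893 MIP nuclei were compared. With 1 library per group there is no replicate check of any difference and no test was made; every value below describes these 2 libraries. Intervals are exact 95% intervals and cover counting error only.

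The libraries also differed in sex. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254 of mm10), had 200147 UMIs in the control library and 120 in the MIP library, or 1749 and 1.45 CPM, the counts scaled to the total of each library. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 37 UMIs in the control library and 39273 in the MIP library, or 0.323 and 473 CPM. The control library thus held female nuclei and the MIP library male nuclei, and every ratio of MIP to control below is also a ratio of male to female.

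The shares of neuroblast-like and cycling progenitor-like nuclei were lower in the MIP library, and the shares of microglia-like and excitatory neuron-like nuclei were higher. Cycling progenitor-like nuclei made up 2.52% (2.27 to 2.79) of control nuclei and 1.80% (1.56 to 2.07) of MIP nuclei, a log2 ratio of -0.49 (-0.75 to -0.23). The fall lay in their cluster 18, at 2.14% and 1.35%. Their cluster 26, led by Egfr, was at 0.385% and 0.450%, a log2 ratio of 0.22 (-0.36 to 0.80). Neuroblast-like nuclei, the migrating newborn neurons of the zone, made up 7.03% (6.62 to 7.46) and 6.27% (5.82 to 6.74), a log2 ratio of -0.17. Microglia-like nuclei, the resident macrophages of the brain, made up 2.05% (1.82 to 2.29) and 3.23% (2.91 to 3.58), a log2 ratio of 0.66 (0.43 to 0.89). Interneuron-like nuclei made up 3.33% and 4.79%, and spiny projection neuron-like nuclei, the main neurons of the neighbouring striatum, 22.6% and 27.8%. Excitatory neuron-like nuclei made up 6.82% and 12.6%. Their rise was largest in clusters 11, at 1.46% and 3.93%, and 12, at 1.48% and 3.74%. Both were named on 3 markers among the top 60 genes, with 0 among the top 10. Cluster 15 was at 1.88% and 2.74%, cluster 17 at 1.66% and 2.02%, and cluster 30 at 0.337% and 0.156%.

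The denominator bore on several of these shares. Unnamed clusters of low depth held 3621 control nuclei, or 24.9%, and 721 MIP nuclei, or 6.62%. These clusters went opposite ways: cluster 0 held 3485 control and 55 MIP nuclei, and cluster 9 held 136 and 666. Without them, an alternative chosen after seeing the data, the cycling progenitor-like share was 3.36% in the control library and 1.93% in the MIP library, and the neuroblast-like share 9.36% and 6.71%. The microglia-like share was then 2.73% and 3.46%, the excitatory neuron-like share 9.08% and 13.5%, and the interneuron-like share 4.44% and 5.13%. Astroglia-like nuclei made up 8.04% of control and 9.89% of MIP nuclei over all nuclei, and 10.7% and 10.6% without the low-depth clusters. Oligodendrocyte precursor-like nuclei made up 5.43% and 6.55% over all nuclei, and 7.23% and 7.02% without them, and spiny projection neuron-like nuclei 30.1% and 29.8%. Within every class compared the MIP nuclei were shallower; neuroblast-like nuclei had a median depth of 3386 UMIs in the control and 2390 in the MIP library.

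Within lineages the same direction held for the later stages. Cycling progenitor-like nuclei were 14.3% of the astroglia-like, cycling and neuroblast-like nuclei together in the control library and 10.02% in the MIP library, a log2 ratio of -0.52 (-0.77 to -0.26). Neuroblast-like nuclei were 39.98% and 34.9% of that lineage, a log2 ratio of -0.20 (-0.34 to -0.05). Astroglia-like nuclei were 45.7% and 55.1% of it and bear on both shares. Over all nuclei their cluster 5 was at 4.81% and 6.87%, cluster 10 at 2.89% and 2.75%, and cluster 28 at 0.330% and 0.266%. The lineage shares alone therefore do not separate fewer later-stage nuclei from more nuclei of cluster 5. Differentiating oligodendrocyte-like nuclei, which have left the precursor state and begin to make myelin, were 20.9% (18.4 to 23.6) of the oligodendrocyte lineage in the control library and 15% (12.7 to 17.6) in the MIP library. Over all nuclei they made up 1.44% and 1.16%, with a log2 ratio of -0.31 (-0.64 to 0.01) that was not distinguishable from 0 at this depth. Without the low-depth clusters they made up 1.91% and 1.24%, a log2 ratio of -0.63 (-0.96 to -0.30).

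**Figure D1:**
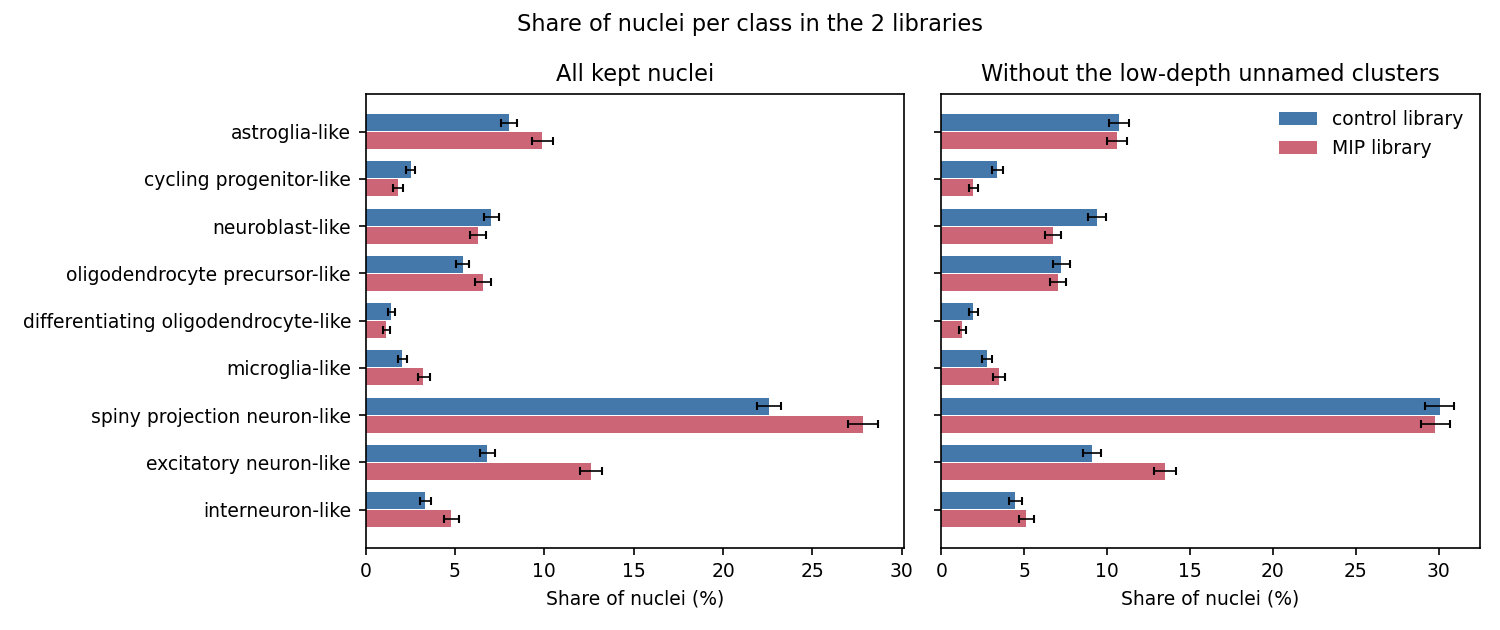
Share of nuclei in percent for the 9 classes compared, in the control and the MIP library, over all kept nuclei and without the unnamed low-depth clusters; bars are shares of 1 library each and error bars are exact 95% binomial intervals. Cycling progenitor-like nuclei were at 2.52% and 1.80% over all nuclei, and astroglia-like nuclei were higher in the MIP library only over all nuclei (8.04% and 9.89%).

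The share of nuclei with a cell cycle transcript was lower in the MIP library among oligodendrocyte precursor-like and microglia-like nuclei. A UMI of Mki67, Top2a or Cenpf, genes of dividing cells, was found after thinning each nucleus to 2000 UMIs in 20.9% (18.1 to 24.0) of control and 14.4% (11.9 to 17.3) of MIP oligodendrocyte precursor-like nuclei, a log2 ratio of -0.54 (-0.91 to -0.17). In microglia-like nuclei the shares were 22.1% (17.4 to 27.5) and 12.6% (8.96 to 17.1), a log2 ratio of -0.81. In astroglia-like nuclei they were 4.65% and 2.59%, a log2 ratio of -0.84 (-1.58 to -0.14). The background in spiny projection neuron-like nuclei, which do not divide, was 3.11% and 2.65%, and the astroglia-like share of the MIP library lay at that background. Neuroblast-like nuclei, at 6.21% and 4.68%, had a log2 ratio of -0.41 (-1.17 to 0.30), and cycling progenitor-like nuclei were at 80.3% and 72.0%, with a log2 ratio of -0.16 (-0.47 to 0.14). With at least 2 such UMIs per nucleus the log2 ratio was -0.53 (-1.07 to 0.0042) in precursor-like, -0.61 (-1.38 to 0.14) in microglia-like and -1.37 (-4.71 to 1.11) in astroglia-like nuclei, so that each interval then included 0.

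Without thinning the shares were 30% and 20.6% in oligodendrocyte precursor-like, 25.8% and 13.6% in microglia-like, 10.01% and 4.18% in astroglia-like, 11.3% and 5.71% in neuroblast-like, 90.2% and 77.0% in cycling progenitor-like and 15.7% and 10.1% in spiny projection neuron-like nuclei. Median depths in the control and the MIP library were 5293.5 and 4268 UMIs in precursor-like, 3108 and 2662 in microglia-like, 5076 and 3652 in astroglia-like, 4819 and 3551 in cycling progenitor-like and 10500 and 7806.5 in spiny projection neuron-like nuclei. Thinning left out nuclei below 2000 UMIs: 2 control and 28 MIP precursor-like, 18 and 75 microglia-like, 8 and 74 astroglia-like, 25 and 192 neuroblast-like, 2 and 14 cycling progenitor-like, and 5 and 46 spiny projection neuron-like nuclei.

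**Figure D2:**
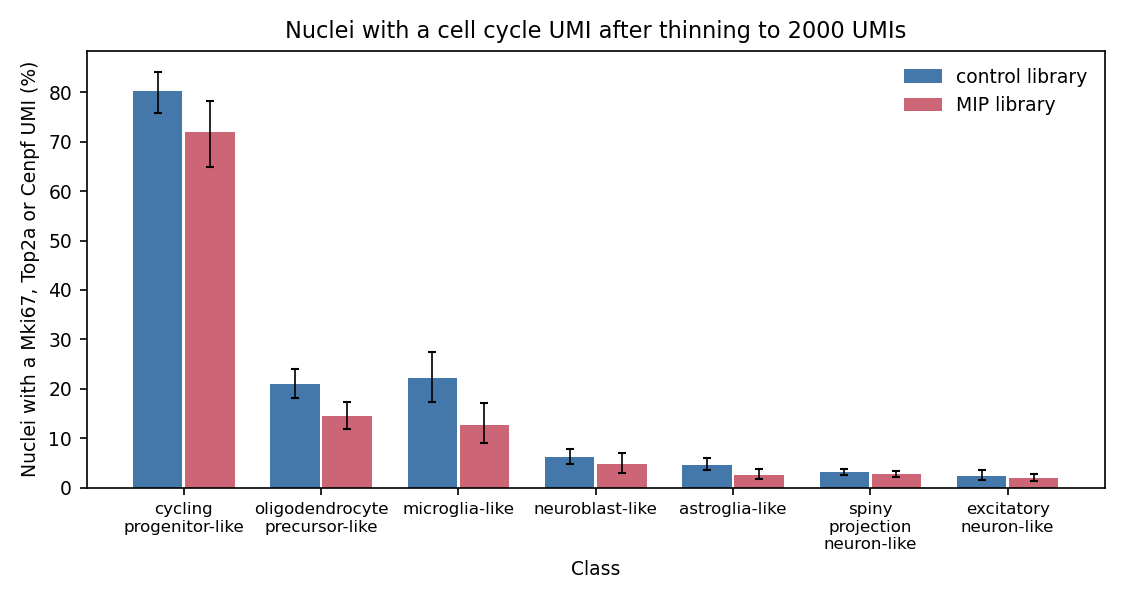
Percent of nuclei per class with a UMI of Mki67, Top2a or Cenpf after thinning to 2000 UMIs, in the control and the MIP library; bars are shares of 1 library each and error bars are exact 95% binomial intervals. Oligodendrocyte precursor-like nuclei were at 20.9% and 14.4% and microglia-like nuclei at 22.1% and 12.6%, above the 3.11% and 2.65% of spiny projection neuron-like nuclei.

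Microglia-like nuclei of the MIP library carried more RNA of cytokine-induced genes and less of genes that mark resting microglia. Of 12 measured acute phase and STAT3 genes, 8 were at least 1.5 times higher and 0 lower, with a median log2 ratio of 1.74. Socs3, the feedback inhibitor induced by STAT3 (chromosome 11, 117966079 to 117970047 of mm10), had 3 UMIs in the control and 122 in the MIP library, a log2 ratio of 5.40 (3.82 to 7.70). Stat3 itself had 109 and 343 UMIs, a log2 ratio of 1.71 (1.39 to 2.03), Bcl6, a transcriptional repressor, 2.81 (1.93 to 3.82), or 1.78 with classes from marker scores, and the complement gene C4b, with 3 and 42 UMIs, 3.86 (2.22 to 6.20). Pim3 had 20 and 13 UMIs and a log2 ratio of -0.57 (-1.70 to 0.51). The list's median lay at the 100th percentile of 10000 random lists of the same size and mean expression, as a description of these libraries; such percentiles are meant in this sense throughout.

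Neighbouring immune lists were displaced the same way in microglia-like nuclei. They share members, such as C4b in the acute phase and the complement list, and are not separate results. The NF-kB and cytokine list had 10 of 20 members higher and 2 lower, a median of 0.59 at the 100th percentile, led by Bcl3 at 3.42 (2.30 to 4.78) and Birc3, an inhibitor of apoptosis, at 2.43, while the growth factor gene Csf1 was at -1.45 (-2.03 to -0.90). Complement and phagocytosis genes had 7 of 15 higher and 0 lower, with a median of 0.58; C1qb was at 0.80 (0.61 to 0.99). Interferon-response genes had 11 of 25 higher and 3 lower, with a median of 0.41; Irgm1 was at 2.05 (0.60 to 3.82) and B2m at -0.80 (-1.25 to -0.35). The activated-microglia list had 5 higher and 6 lower of 21, with a median of 0.01 at the 61.9th percentile: Apoe, a lipid carrier, was at 1.46 (1.37 to 1.55) and the growth factor Igf1 at 1.04 (0.79 to 1.30), but Ctsd at -0.55, and Gpnmb, with 27 and 0 UMIs, was at least 8.66-fold lower against a floor of 3 UMIs over the class, or 6.58-fold by the exact interval. Reactive-astrocyte genes, which include several cytokine targets, had 7 of 11 higher in microglia-like nuclei, with a median of 0.82, or -0.36 over members with at least 1 UMI.

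The homeostatic list was lower, with 8 of 15 members lower and 0 higher and a median of -0.62 at the 0.01th percentile. Siglech was at -1.96 (-2.23 to -1.70), Sall1, a transcription factor of microglial identity, at -1.68 (-2.08 to -1.30), and Gpr34 at -1.56 (-1.93 to -1.20), whereas P2ry12, the microglial ADP receptor, was at 0.09 (-0.04 to 0.23) and Csf1r at 0.18 (0.03 to 0.34). Cell cycle genes of the G2 and M phases had 34 of 50 members lower and 0 higher, with a median of -0.85; Mki67 was at -1.02 (-1.58 to -0.49). By rank, the 5 genes highest in the MIP library were Xdh, Socs3, Lifr, Ccnd3 and Gcnt2. Xdh, the xanthine dehydrogenase gene, had 1 and 97 UMIs, a log2 ratio of 6.65 (4.14 to 11.97), and Lifr, a receptor subunit of the interleukin 6 family, 78 and 516 UMIs, a ratio of 2.78 (2.43 to 3.14). Thinning to 2000 UMIs put Socs3 at 4.58, and classes from marker scores Xdh at 5.07; without doublet removal Hist1h1b was at -2.32. Myo1d at -2.87, Hist1h1b at -3.04, Slc12a2 at -2.20, Siglech and Ifitm10 at -2.39 ranked lowest. Genes of other classes were lower in microglia-like nuclei: the neuroblast list had 9 of 13 members lower and 0 higher, with a median of -0.79, and the neural stem cell list 8 of 11 lower, with a median of -1.39. The class rested on 298 control and 352 MIP nuclei, and cluster 14 held 86.2% and 94.6% of them. Cluster 31, with the cell cycle gene Cenpe among its top 10 genes, held 13.8% and 5.40%. The lower G2 and M phase list was not separated from this difference in cluster shares.

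**Figure D3:**
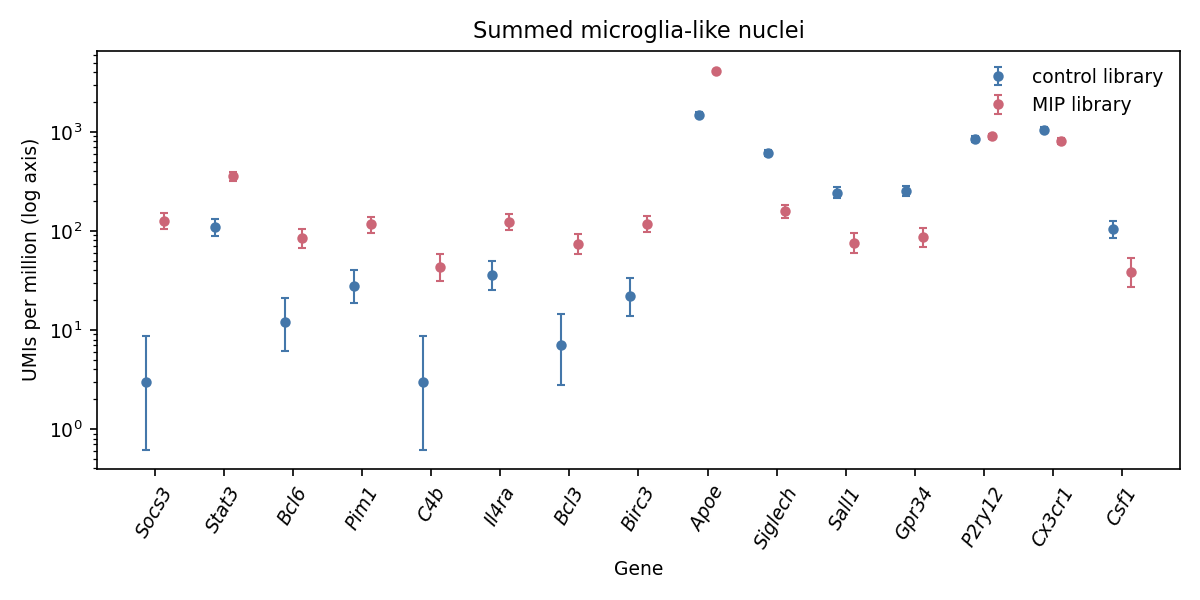
CPM of UMIs summed over microglia-like nuclei, on a log axis, for 15 genes in the control and the MIP library; points are sums of 1 library each and error bars are exact 95% Poisson intervals. Socs3 had 3 and 122 UMIs, Siglech 614 and 152, and P2ry12 lay close together in the 2 libraries.

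Astroglia-like nuclei, the class that holds the stem cells of the zone and parenchymal astrocytes, carried more RNA of glucocorticoid-induced and clock genes in the MIP library. Fkbp5, a chaperone gene induced through the glucocorticoid receptor (chromosome 17, 28399094 to 28517527 of mm10), had 102 UMIs in the control and 735 in the MIP library, or 15.6 and 172 CPM, and was 11.1-fold higher, a log2 ratio of 3.47 (3.17 to 3.78), or 2.06 without doublet removal. Of 22 glucocorticoid-response genes 11 were at least 1.5 times higher and 0 lower, with a median log2 ratio of 0.66 at the 100th percentile; Tsc22d3 was at 1.64 (1.31 to 1.98), Zbtb16 at 1.46 (1.10 to 1.82) and the receptor gene Nr3c1 at -0.43 (-0.63 to -0.24). Of 19 circadian clock genes 12 were higher and 0 lower, with a median of 0.78 at the 100th percentile; Nr1d1, a repressor of the clock loop, was at 2.16 (1.75 to 2.59), Per1 at 1.48 (1.22 to 1.73), Per2 at 1.32 (1.04 to 1.59) and Arntl at 0.15 (0.01 to 0.30). Per1 is a member of both lists. TMM scaling would put each log2 ratio in astroglia-like nuclei 0.11 higher.

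Acute phase and STAT3 genes had 8 of 14 members higher and 0 lower in astroglia-like nuclei, with a median of 0.66; Pim3 was at 1.27 (0.86 to 1.68) and Stat3 at 0.83 (0.66 to 0.997). The reactive-astrocyte list did not stand apart, with 3 of 16 higher, 3 lower and a median of -0.17 at the 51.9th percentile; Gfap, the filament gene of reactive astrocytes and stem cells, was at -0.10 (-0.26 to 0.05) and Serpina3n, with 21 and 10 UMIs, at -0.45 (-1.70 to 0.70), or 0.15 without doublet removal. Lcn2, a secreted acute phase protein, was counted over all nuclei only, with 0 and 8 UMIs, and was at least 3.68-fold higher there against a floor of 3 UMIs over the library, or 2.35-fold by the exact interval. Hedgehog pathway genes had 0 of 14 higher and 2 lower, with a median of -0.09 at the 44.2th percentile, or 0.02 after TMM scaling. Among them Gli1, a target and effector of the pathway, was at -0.05 (-0.56 to 0.44) and Hhip at -0.12 (-0.51 to 0.25), and neither difference was distinguishable from 0 at this depth; Ptch1, the receptor and a target, was at -0.45 (-0.57 to -0.34). Neural stem cell genes had 1 of 16 higher and 2 lower, with a median of -0.05, and Notch genes 2 of 16 higher, with a median of 0.08; Hes1 was at 1.05 (0.85 to 1.26) and Hopx at -0.73 (-1.21 to -0.26).

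Genes of other classes also differed in astroglia-like nuclei. Neuroblast genes, which mark another class, had 9 of 17 members lower and 0 higher, with a median of -0.64; Dlx1 was at -1.73 (-2.31 to -1.18). G2 and M phase genes had 19 of 39 lower and 0 higher, with a median of -0.49. Complement genes had 4 of 11 higher and 0 lower, with a median of 0.53. Among them C1qb, a gene of microglia, was at 1.09 (0.53 to 1.66), and Mertk, a phagocytic receptor that astrocytes use, at 0.997 (0.91 to 1.08). Mertk is also a member of the glucocorticoid list, so it counts in both results. Likewise Cebpd is in the acute phase and the glucocorticoid list, and Fkbp5 in the glucocorticoid and the reactive-astrocyte list.

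Among genes that reached at least 20% of the level of the class with the highest value, Gm22146, Nr1d1, Spsb1, Kcnt1, Gm26917, Ciart, Rhou, Per1, Acsl3 and Hif3a ranked highest in MIP astroglia-like nuclei, with log2 ratios of 4.02, 2.16, 2.03, 1.74, 1.47, 1.86, 1.53, 1.48, 1.23 and 1.32. Fkbp5 and Tsc22d3, at 16.1% and 12.7% of that level, and Dlx1, at 8.39%, stood outside the ranking by this limit, although their intervals lay as far from 0 as those of ranked genes. Without doublet removal Gm22146 was at 2.19 and Kcnt1 at 0.66. In the low-depth nuclei Gm22146 was at 3.55 (1.19 to 6.24), Gm26917 at 2.08 (1.91 to 2.24) and Kcnt1 at 0.78 (0.30 to 1.25). The intervals of the other highest-ranked genes included 0 in the low-depth nuclei. Those nuclei were mostly cluster 0 in the control and cluster 9 in the MIP library, so their ratios also compare different clusters. Over the other classes compared, the median log2 ratio was 1.06 for Gm22146, 0.89 for Ciart, 0.78 for Per1, 0.46 for Gm26917 and 0.38 for Nr1d1. It was 0.20 for Rhou, 0.16 for Acsl3, 0.08 for Spsb1 and 0.07 for Kcnt1. Cluster 5 held 59.9% of the class in the control and 69.5% in the MIP library. Lowest by rank were Pmch, Oxt, Gm48765, Avp, Inhba, Gm15270, Cmss1, Pter, AY036118 and Gm39323. Inhba, which encodes a subunit of activins, had 89 and 13 UMIs, a log2 ratio of -2.15 (-3.12 to -1.31), or -1.16 without doublet removal and -2.91 with classes from marker scores. Pmch, Oxt and Avp encode peptides of hypothalamic neurons and were lower in most classes: over all nuclei Pmch had 1561 and 9 UMIs, Oxt 894 and 69, and Avp 3785 and 552. Cmss1 and AY036118, at -1.60 and -1.56 over all nuclei, were likewise among the lowest in most classes. With Gm42418 they were treated as ribosomal RNA-like quality genes, and all of them were among the top 10 genes of the low-depth cluster 0. Their lower values were not separated from a difference in such RNA between the libraries.

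**Figure D4:**
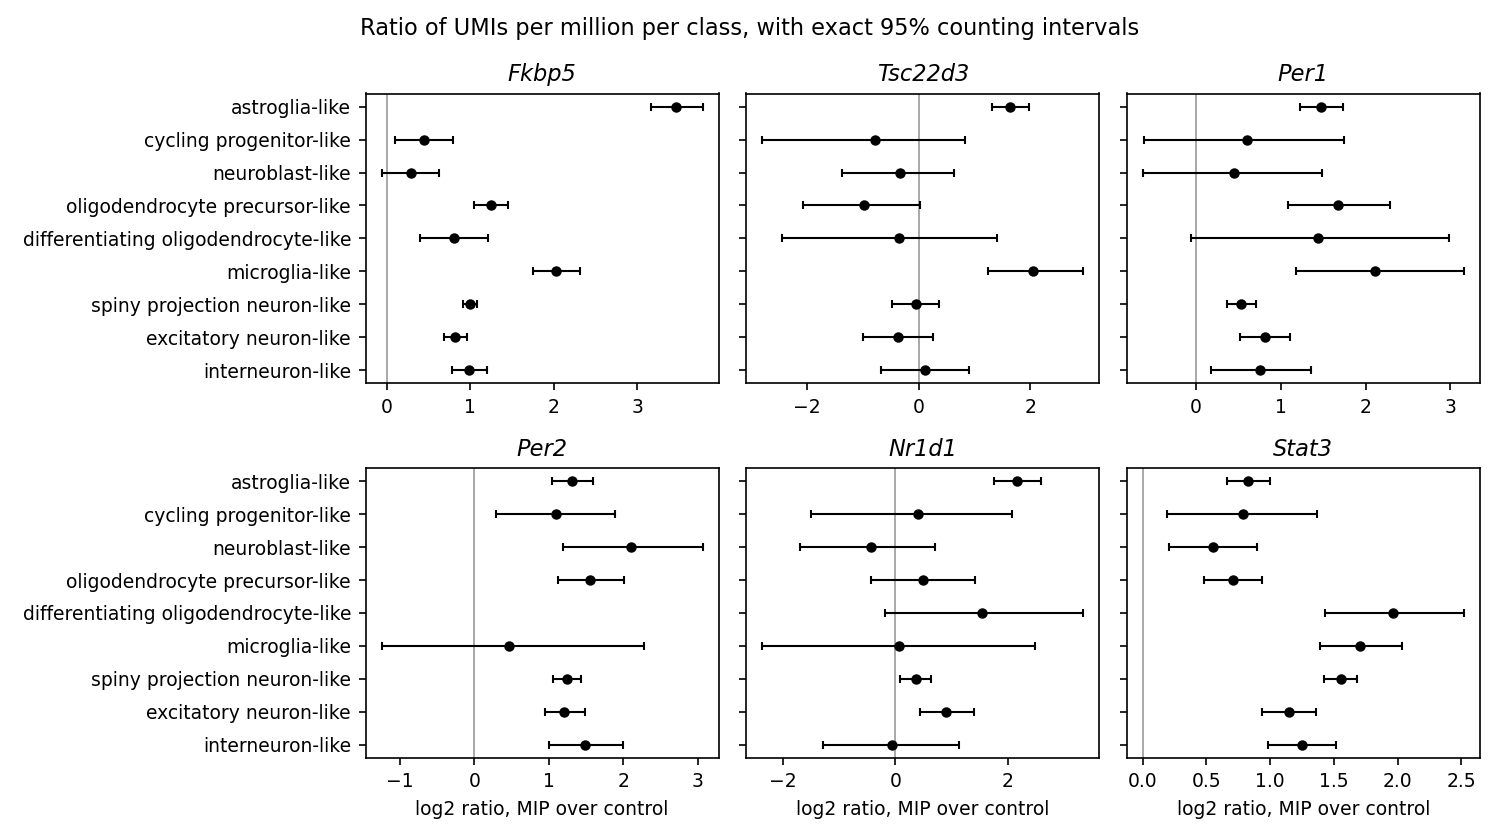
Log2 ratio of CPM, MIP over control library, for Fkbp5, Tsc22d3, Per1, Per2, Nr1d1 and Stat3 in each class; points are ratios of 1 library to 1 library and error bars are exact 95% intervals of the ratio, with the grey line at 0. Fkbp5 was at 3.47 in astroglia-like nuclei and at 0.29 in neuroblast-like nuclei, and Stat3 lay above 0 in all 9 classes.

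Clock genes were displaced upward in every class compared except interneuron-like nuclei, Fkbp5 was higher in most classes and Stat3 in all 9. The clock list's median was 0.60 in cycling progenitor-like, 0.53 in microglia-like, 0.50 in differentiating oligodendrocyte-like, 0.29 in oligodendrocyte precursor-like, 0.28 in neuroblast-like, 0.23 in spiny projection neuron-like and 0.21 in excitatory neuron-like nuclei, above the 95% range of random lists in each. In interneuron-like nuclei it was 0.09, at the 97.0th percentile and inside that range. Fkbp5 was at 2.03 (1.76 to 2.31) in microglia-like, 1.25 (1.04 to 1.45) in oligodendrocyte precursor-like, 0.995 in spiny projection neuron-like, 0.99 in interneuron-like, 0.82 in excitatory neuron-like and 0.81 in differentiating oligodendrocyte-like nuclei, but at 0.45 (0.10 to 0.80) in cycling progenitor-like and 0.29 (-0.06 to 0.63) in neuroblast-like nuclei. The glucocorticoid list as a whole did not follow in each class. Its median was 0.30 in differentiating oligodendrocyte-like, 0.22 in microglia-like, 0.12 in oligodendrocyte precursor-like and 0.10 in interneuron-like nuclei, at or above the 97.8th percentile in each, but -0.05 in spiny projection neuron-like, -0.18 in neuroblast-like, -0.36 in excitatory neuron-like and -0.39 in cycling progenitor-like nuclei, each inside the 95% range of random lists. In differentiating oligodendrocyte-like nuclei it rested on 9 members, 2 higher and 1 lower, and was -0.37 with classes from marker scores, -0.28 over members with at least 100 UMIs, -0.072 as a mean of single nuclei and -0.049 after thinning to 2000 UMIs. In interneuron-like nuclei it was -0.10 as a mean of single nuclei. Tsc22d3 was at 2.05 (1.25 to 2.94) in microglia-like and -0.97 (-2.06 to 0.02) in oligodendrocyte precursor-like nuclei.

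The acute phase and complement lists were displaced upward outside microglia-like and astroglia-like nuclei too. Acute phase and STAT3 genes had a median of 0.39 in cycling progenitor-like, 0.36 in oligodendrocyte precursor-like, 0.33 in interneuron-like, 0.22 in spiny projection neuron-like and 0.08 in excitatory neuron-like nuclei, above the 95% range of random lists in each, with 2 of 7, 3 of 9, 3 of 9, 5 of 15 and 2 of 12 members higher and 1, 0, 0, 1 and 2 lower. The medians of 0.35 in differentiating oligodendrocyte-like and 0.27 in neuroblast-like nuclei lay inside that range. As a mean of single nuclei the value was 0.02 in cycling progenitor-like nuclei, with classes from marker scores 0.02 in interneuron-like nuclei, and over members with at least 1 UMI -0.11 in excitatory neuron-like nuclei. Complement and phagocytosis genes had a median of 0.55 in oligodendrocyte precursor-like, 0.44 in cycling progenitor-like, 0.37 in spiny projection neuron-like, 0.35 in neuroblast-like and 0.24 in excitatory neuron-like nuclei, above the range in each, and 0.05 in interneuron-like nuclei, inside it. No doublet removal put this list at 0.05 in oligodendrocyte precursor-like nuclei, and thinning to 2000 UMIs at -0.46 in excitatory neuron-like nuclei.

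Cycling progenitor-like nuclei, fewer in the MIP library, differed little in Mki67 relative to the class total, while G2 and M phase genes as a list were slightly lower. Mki67 had 429 and 160 UMIs, a log2 ratio of -0.03 (-0.30 to 0.23). Mki67 and other cell cycle genes are among the markers that named this class, so its level here says little on proliferation. G2 and M phase genes had 1 of 54 members higher and 4 lower, with a median of -0.14 at the 0.1th percentile, and S phase genes 5 of 42 higher and 2 lower, with a median of 0.13 at the 94.9th percentile. Ptch1 was at -0.67 (-1.02 to -0.34), Gli1, with 25 and 8 UMIs, at -0.25 (-1.61 to 0.94), and the hedgehog list's median was -0.13. Pdcd4, a translation inhibitor, ranked highest, with a log2 ratio of 1.27 (0.99 to 1.56), before Stxbp5l at 1.16, Tbc1d9 at 1.29, Zfp948, Iffo1, Nexmif, Nln, Ccdc88c, Mid1 and Slc38a1. Lowest were Dcun1d2, with 69 and 3 UMIs and a log2 ratio of -3.13 (-5.44 to -1.52), Gm29260, Cmss1, AY036118, the bicarbonate transporter Slc4a4 at -1.22, the linker histone genes Hist1h1b at -1.48 and Hist1h1e at -1.41, Gm11266, Rwdd1 and Jpx, a noncoding RNA gene next to Xist, at -1.25. With classes from marker scores Pdcd4 was at 0.67, after thinning to 2000 UMIs Hist1h1b was at -2.21, and with clusters weighted equally Dcun1d2 was at -2.17 and Slc4a4 at -0.48. Integrated stress response genes had 7 of 16 members lower and 0 higher, with a median of -0.51, or 0.16 over members with at least 100 UMIs; the cystine transporter gene Slc7a11 was at -1.78 (-3.04 to -0.72). Cluster 18 held 84.7% of the class in the control and 75% in the MIP library. Within it, 87.4% of control and 87.8% of MIP nuclei carried a cell cycle UMI after thinning. The lower G2 and M phase list of the class was not separated from this difference in cluster shares.

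Neuroblast-like nuclei showed little displacement of their own program. Many of its genes, among them Dcx, Sp8, Sp9 and Dlx genes, are also markers that named the class. A small displacement was therefore partly set by how the class was chosen. Of 17 neuroblast genes 1 was higher and 1 lower, with a median of -0.01 at the 30.4th percentile. Dcx, a microtubule protein of migrating neurons, had 2942 and 1758 UMIs, a log2 ratio of 0.36 (0.27 to 0.45), Sp9 was at 0.69 (0.49 to 0.89) and Dlx6 at -0.68 (-1.06 to -0.32). Axon guidance and migration genes had 2 of 23 higher and 3 lower, with a median of -0.01; Sema3c was at -1.74 (-2.75 to -0.86). Highest by rank were Gm20646 at 1.48, Dusp16 at 1.43, Gk5 at 1.64, Pkia, an inhibitor of protein kinase A, at 1.14, Dennd2a, Pik3cb, Dbt, Tbc1d23, Laptm4b and Tspan7. Lowest were Pmch, Avp, C79798 at -1.38, Mrs2 at -2.07, Cmss1, Gm48742, the adhesion genes Igsf11 at -1.48 and Cdh12 at -1.43, Gm12064, and Fabp7, a fatty acid-binding protein of radial glia, at -1.29 (-1.55 to -1.04). Cdh12 was at -0.40 without doublet removal, -0.52 with at least 1000 genes and -0.58 with classes from marker scores, which put Mrs2 at -0.75.

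Oligodendrocyte precursor-like nuclei of the MIP library carried less cell cycle RNA and more RNA of cholesterol synthesis and immediate early genes. G2 and M phase genes had 36 of 54 members lower and 0 higher, with a median of -0.72; Cenpf had 290 and 66 UMIs, a log2 ratio of -1.65 (-2.06 to -1.26), and Mki67 was at -0.55 (-0.89 to -0.21). Cluster 23, in which 90.7% of control and 95.7% of MIP nuclei carried a cell cycle UMI after thinning, held 12.3% of the class in the control and 6.72% in the MIP library; with its clusters weighted equally, an alternative chosen after seeing the data, the list's median was -0.10, Cenpf was at -0.98 and Mki67 at 0.34. With at least 1000 genes Mki67 was at -1.24. Cholesterol synthesis genes had 8 of 23 higher and 2 lower, with a median of 0.45 at the 100th percentile: Hmgcs1, an early enzyme of the pathway, was at 0.56 (0.38 to 0.73) and Pmvk at -0.80 (-1.31 to -0.32). Immediate early genes had 7 of 17 higher and 3 lower, with a median of 0.36; Egr1 was at 1.46 (1.08 to 1.85) and Jund at -0.71.

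The neuroblast list was lower in this class too, with 8 of 17 members lower, 0 higher and a median of -0.57. The identity genes of precursors differed little. Several of them, among them Pdgfra and Olig2, are also markers that named the class, so this was partly set by how the class was chosen. The oligodendrocyte specification list had 1 of 12 members higher and 2 lower, with a median of -0.13 at the 14.1th percentile; Olig2 was at -0.02 (-0.19 to 0.15), Pdgfra, the growth factor receptor of precursors, at -0.09 (-0.16 to -0.03), or 0.0024 after TMM scaling, and Gpr17 at -0.82 (-1.06 to -0.58). By rank Klf10, at 1.89 (1.51 to 2.27), was highest, before Morn3 at 1.52, Per2 at 1.56, Egr1, Rasl11a at 1.40, Fkbp5, Trib1 at 1.55, Hes1 at 1.21 and Ell2. Lowest were 4930588J15Rik at -2.72, Pif1, a DNA helicase gene, at -2.45, Hist1h1b at -2.27, B230217J21Rik at -1.81, Csmd2os, Cmss1, Cenpf, Lrrc8dos, Avp at -1.75 and AY036118. Without doublet removal Avp was at 0.012, Pif1 at -0.95 and 4930588J15Rik at -1.88, while thinning to 2000 UMIs put 4930588J15Rik at -4.71. Hist1h1b was at -3.40 with classes from marker scores and at -1.42 with clusters weighted equally, which put Pif1 at -1.66.

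Differentiating oligodendrocyte-like nuclei had lower RNA of some genes of the differentiation step and of myelin, with Mbp going the other way. Gpr17, a receptor of newly committed oligodendrocytes, had 464 and 96 UMIs, a log2 ratio of -1.16 (-1.49 to -0.84), Mobp, a myelin gene, 336 and 48 UMIs, a ratio of -1.69 (-2.16 to -1.25), and Mbp 4663 and 3044 UMIs, a ratio of 0.50 (0.43 to 0.57). The myelin list had 0 of 11 members higher and 3 lower, with a median of -0.12 at the 16.7th percentile, and the specification list 0 of 13 higher and 3 lower, with a median of -0.10. Stat3 ranked highest, at 1.97 (1.43 to 2.52), before Gm32647, Rffl at 1.28, Tox3 at 1.29, Dner, Afdn, Gng4, Mbtps1, Smad3, a mediator of transforming growth factor signalling, at 1.10, and Cyth1. Gm32647 was at 1.61 (1.11 to 2.13), or -0.075 with classes from marker scores, which put Dner at 0.40, Gng4 at 0.43, Smad3 at 0.33 and Jak1 at -0.94. After Mobp the lowest were Rnf43 at -2.41, Zeb2 at -1.19, Kif19a, Cmss1, Vegfa at -1.72 (-2.57 to -0.96), Jak1 at -1.90, AY036118, Tmsb10 and Gpr17. The class rested on 209 control and 126 MIP nuclei.

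Neuron-like and cycling progenitor-like nuclei had lower cholesterol synthesis RNA, opposite to the precursors. The list's median was -0.71 in excitatory neuron-like nuclei, with 14 of 23 members lower and 0 higher, -0.52 in interneuron-like nuclei, with 11 lower and 0 higher, and -0.50 in spiny projection neuron-like nuclei, with 7 lower and 1 higher, at or below the 0.02th percentile in each. Hmgcs1 was at -1.14 (-1.27 to -1.02), -0.92 (-1.15 to -0.69) and -0.83 (-0.92 to -0.74) in these 3 classes. In cycling progenitor-like nuclei 8 of 23 members were lower and 0 higher, with a median of -0.37 at the 0.57th percentile, or -0.14 without doublet removal. In microglia-like nuclei 8 of 19 were lower and 0 higher, with a median of -0.44 inside the 95% range of random lists, and in astroglia-like, neuroblast-like and differentiating oligodendrocyte-like nuclei the medians of -0.19, -0.12 and 0.05 lay inside it too. TMM scaling would put each ratio 0.15 higher in excitatory neuron-like, 0.11 in interneuron-like and 0.13 in spiny projection neuron-like nuclei. The clusters of excitatory neuron-like nuclei had other proportions in each library: cluster 11 held 21.5% of the class in the control and 31.2% in the MIP library, cluster 12 21.7% and 29.7%, cluster 15 27.5% and 21.8%, and cluster 17 24.4% and 16.05%.

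By rank, spiny projection neuron-like nuclei were highest in the MIP library for Cacng6 at 2.85, Tchh, Tex45, Per2 at 1.25 and Slc25a30, and lowest for Pmch, Oxt, Serpine3 at -3.16, Avp and Lrrc8dos. Excitatory neuron-like nuclei were highest for Adam18 at 3.26, Qrfpr, the clock repressor gene Cry1 at 1.41 (1.24 to 1.58), Unc13c and Tafa2, and lowest for Pmch, the serotonin transporter gene Slc6a4 at -3.46, or -4.32 after thinning to 2000 UMIs, Vgll3, Serpine3 and Ovol2. Interneuron-like nuclei were highest for Per2 at 1.49, or 0.85 after thinning to 2000 UMIs, Stat3 at 1.25 (0.99 to 1.51), Cdh9 at 1.04 (0.94 to 1.14), Reln at 0.97 (0.89 to 1.06) and Hspa14, and lowest for Gm17484 at -2.30, or -1.29 with classes from marker scores, B230217J21Rik, Zfp931, Cmss1 and 1700080N15Rik. Cluster 13 held 50.9% of interneuron-like nuclei in the control and 65.9% in the MIP library, and with clusters weighted equally Cdh9 was at 0.82 and Reln at 0.65. Stat3 in spiny projection neuron-like nuclei, at 15.6% of the level of the class with the highest value, stood outside the ranking.

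Over all nuclei, values mix the makeup of each library with expression within classes, and TMM scaling would put each log2 ratio 0.17 higher. Gm29650, with 0 and 108 UMIs, ranked first in the MIP library and is Y-linked. Next were the chemokine gene Ccl8 at 2.91 (2.11 to 3.82), Ms4a4a at 2.11, the Fc receptor gene Fcgr2b at 1.96 (1.72 to 2.21) and Adam18. Lowest were Pmch at -6.97, Gm43824, Oxt and the histone gene Hist1h3c at -3.18. As a mean of single nuclei Pmch was at -7.81, Ccl8 at 1.68 and Adam18 at 1.24. Fkbp5 was at 1.15 (1.10 to 1.19). Nuclear-encoded oxidative phosphorylation genes had 30 of 42 members lower and 0 higher, with a median of -0.80, and their median lay at the 0th percentile in each of the 9 classes, between -0.63 in microglia-like and -0.43 in neuroblast-like nuclei. Signs of cytoplasmic RNA differed beside them: mitochondrial UMIs made up 0.618% of the control and 0.423% of the MIP library, ribosomal protein UMIs 1.10% and 0.627%, and Gm42418 was at -1.16.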

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

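The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were used in no comparison and together had 473 CPM in the MIP library against 0.323 CPM in the control library, a signal outside the main measurement that differs between the libraries.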

How the results depend on the processing

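Shares without the low-depth clusters and values with clusters weighted equally were chosen after seeing the data. So were the rule that reads a list's direction against matched random lists, the choice of lists followed and the 12 list medians taken as answering a comparison; this rule was revised 2 times, and other versions gave other numbers of reversals. Of 1758 gene ratios under alternatives 1558 stayed within their interval, 192 moved and 8 reversed. List medians have no interval of counting error. They were read against the spread of matched random lists, placed around each list's own median. Of 979 list medians 902 stayed within that spread, 66 moved and 11 reversed, which says nothing on counting error. Of 93 shares 62 stayed within their interval, 27 moved and 4 reversed. All 15 cell cycle shares stayed within their intervals, which for precursors, microglia and astroglia included 0 with at least 2 UMIs. No alternative adds a library, so none bears on sex or on variation between animals, and depth limits members of few UMIs most. All values are log2 ratios, and where no cause is named the cause was not tested.

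At Leiden resolution 0.5 the shares were 0.46 for astroglia, -0.41 for neuroblasts and -0.46 for spiny projection neurons, reversed from 0.30; at resolution 2, -0.41 for neuroblasts and -0.82 for differentiating oligodendrocytes within their lineage. With the MIP library clustered alone neuroblasts were at -0.38. With at least 1000 genes shares were 0.025 for astroglia, -0.80 for cycling progenitors, -0.72 for neuroblasts, 0.12 for precursors, -0.77 for differentiating oligodendrocytes and 0.39 for microglia; the neuroblast list in neuroblasts was at 0.16 and G2 and M phase genes in precursors at -0.51. Without low-depth clusters, shares were -0.015 for astroglia, -0.012 for spiny projection neurons and -0.043 for precursors, all reversed, and -0.80 for cycling progenitors, -0.48 for neuroblasts and 0.34 for microglia; the smaller control denominator produces this by construction.

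With marker scores in place of clusters, shares were 0.16 for astroglia, -0.75 for cycling progenitors, -0.36 for neuroblasts and 0.38 for microglia; G2 and M phase genes in precursors were at -0.53. Reversed there were interferon genes (-0.22) and synaptic genes (0.047) in cycling progenitors, and glucocorticoid genes (-0.37) and Gm32647 (-0.075) in differentiating oligodendrocytes. Without doublet removal neuroblasts were at -0.39 and G2 and M phase genes in precursors at -0.53, and interferon genes in cycling progenitors (-0.25), Avp (0.012) and Pdgfra (0.038) in precursors reversed. TMM scaling reversed Pdgfra in precursors (0.0024) and Mbp over all nuclei (0.045), by its shift. Means of single nuclei reversed immediate early genes (-0.20), Gli1 (0.0041) and Mbp (0.0033) over all nuclei and glucocorticoid genes in differentiating oligodendrocytes (-0.072). Thinning to 2000 UMIs gave 0.98 for clock genes in astroglia and reversed glucocorticoid genes in differentiating oligodendrocytes (-0.049) and complement genes in excitatory neurons (-0.46). With members of at least 100 UMIs glucocorticoid genes were at 0.89 in astroglia and reversed in differentiating oligodendrocytes (-0.28), as did integrated stress genes in cycling progenitors (0.16); with at least 1 UMI reactive-astrocyte genes in microglia reversed (-0.36). With clusters weighted equally glucocorticoid genes were at 0.87 in astroglia, G2 and M phase genes at -0.10 and Mki67 at 0.34, reversed, in precursors, since this removes the difference in the share of the cycling cluster.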

Other observations

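Fibroblast-like nuclei, of the membranes around the brain, made up 0.392% (0.297 to 0.507) of control and 1.03% (0.847 to 1.24) of MIP nuclei, a log2 ratio of 1.39 (0.92 to 1.88) that rested on 57 and 112 nuclei. Over all nuclei Aldh1a2, a retinoic acid synthesis gene, was at 1.81 (1.52 to 2.12), the acute phase gene Saa3 at 1.74 (1.40 to 2.08) and Casp4, the inflammatory caspase gene, at 1.98. Unnamed cluster 21, led by Lgr5 and Cpa6, held 263 control and 44 MIP nuclei, or 1.81% and 0.404%. Hypothalamic peptide genes beyond those named for astroglia were lower over all nuclei as well: Hcrt had 233 and 52 UMIs and Gnrh1 211 and 17.

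Of the tests below, that of border macrophages was set before its result was seen; those of free RNA, sex, time of day, depth, shallow nuclei and tissue were written after the values they use had been seen. The tests on shallow nuclei were also redone with another bound after a first version, from marker genes, had come out below the control share.

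The first pattern is the higher RNA of acute phase and STAT3 genes in microglia-like nuclei of the MIP library. Free RNA could add no more than its own level, taken here, as an assumption, from the low-depth nuclei of the MIP library; the excess of the 8 higher members was a median of 8.51 times that level (lower quartile 2.56, 7 of 8 members above 1), which argues against free RNA as the whole source. Border macrophages in the class would have to supply 60.3% of its UMIs at the median member, while their markers allowed 6.12% (upper bound 6.49%), with a reference of only 45 nuclei. Sex stays open and cannot be told apart from MIP, since the MIP library had 1.45 CPM of Xist and each library held 1 sex. A response of microglia to circulating cytokines after intestinal perforation remains a hypothesis that these libraries do not test.

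The second pattern is the higher RNA of clock and glucocorticoid-induced genes in astroglia-like nuclei. The excess of the 22 higher members was a median of 1.46 times the level in low-depth nuclei (lower quartile 0.894, 16 of 22 above 1), so free RNA may contribute to part of the members and is not excluded. A different time of day at dissection may also be a source: the clock list's median was above 0 in all 9 classes, the lowest being 0.086 in interneuron-like nuclei, inside the range of random lists, and no time is given in the sources used here. Glucocorticoid genes outside the clock list, 21 members, had a median of 0.53 in astroglia-like nuclei. Neither corticosterone values nor whether it has a daily rhythm at postnatal day 7 are given in the sources used here. Time of day and stress hormone after MIP therefore cannot be told apart here. Sex is confounded with both.

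The third pattern is the lower share of neuroblast-like and cycling nuclei in the MIP library. Within oligodendrocyte precursor-like nuclei the log2 ratio of cell cycle shares at equal depth was -0.54 (-0.91 to -0.17), which argues against depth for that part, though with at least 2 UMIs the interval reached 0.0042. Loss of shallow nuclei is not excluded for the rest: with all 204 MIP barcodes under 500 genes counted as neuroblasts the MIP share would be 7.99%, against 7.03% in the control library, and counted as cycling progenitors 3.60%, against 2.52%, while markers, if these barcodes had the profile of kept nuclei, would allow at most 6.49% and 1.93%. Nuclei never called as barcodes are covered by neither bound. The log2 odds of excitatory to spiny projection neuron-like nuclei differed by 0.58 (0.44 to 0.72), which goes with a difference in the tissue taken. Hypothalamic peptide RNA was also lower in the MIP library. Over all nuclei Pmch had 1561 and 9 UMIs, Oxt 894 and 69, Avp 3785 and 552, and Gnrh1 211 and 17. These values, and the fibroblast-like share of 0.392% and 1.03%, go with such a difference too, but were not part of that test. In the control library Pmch was at 111 CPM in the low-depth nuclei and 13.6 over all kept nuclei, and Avp at 197 and 33.1. The peptide RNA can therefore include free RNA and does not show that hypothalamic nuclei were taken. The dissection, the sex of the animals and an effect of MIP on the germinal zone all stay open.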
